A study of Caenorhabditis elegans with 2 samples.

How the data were processed

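ChIP-seq with an antibody to GFP was carried out on whole L4 hermaphrodites of strain OP312, which carries unc-119(ed3) and the transgene wgIs312 expressing LIR-3 with a C-terminal GFP-FLAG tag, per the labels. Chromatin was sheared by sonication, per the labels. The group has 2 biological replicates, and nothing further in the labels says how separate the cultures were.

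Peak lists in narrowPeak format were used on builds ce11 and ce10. For each build there are 3 relaxed lists, made as input for IDR: 1 per replicate and 1 called on the pooled replicates, with a control alignment, per the submitters' file listing. The optimal IDR list was derived from them. The aligner, the peak caller and their versions are not given in the sources used here, nor are the read length, read number and fragment size. Each peak's signal value is a score that the authors deposited; its scale is not stated and it is not comparable between lists. The deposited −log10 of the q-value was used only to describe the lists. All 552 IDR peaks on ce11 share its highest value, and they are exactly the 552 highest-scoring peaks of the pooled list. The summit position is the deposited offset from the peak start. Broad peaks can hold several summits, each listed as a peak of its own. No read counts were used, so depth is unknown and no interval covers it. A mock or untagged immunoprecipitation and the control reads are not analysed here.

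Gene starts and biotypes were taken from the Ensembl annotation of WBcel235, whose coordinates are those of ce11, and sequence, tRNA isotypes and mitochondrial gene symbols from the RefSeq records of the same assembly. Coordinates are 1-based. The ce10 lists were used only for counts, the X share and replicate agreement, and no coordinate was converted between builds.

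A summit was assigned to every gene with its start in the window, from 500 bp upstream to 200 bp downstream. The control set was the 19684 peaks of the pooled relaxed list that no IDR peak overlaps by 1 bp or more. Shares were compared by two-sided Fisher's exact test with the exact conditional 95% interval of the odds ratio, and adjusted by the Benjamini-Hochberg method over 11 biotypes or 25 gene lists. Gene lists used as background the protein-coding genes with a pooled relaxed summit in the window. Motifs, 15 in number, and all 6-mers on either strand were counted within 50 bp of the summit and in equal windows 300 bp to the left, and compared by McNemar's exact test. Peak positions were also compared with 1000 circular shifts along each chromosome, and correlations with 100000 permutations. The peak is the unit of these tests. For the gene lists and for comparisons that count genes, the gene is the unit. Neighbouring peaks and peaks of clustered genes are not independent, and the replicates enter through the IDR list and through the analyses that use 1 replicate's list alone.

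The gene lists, motifs, windows and the rule for named genes were fixed before the data were examined. The rule names lir-3, lir-1, lir-2, lin-26 and unc-119, up to 2 genes at each of the 15 strongest peaks with a gene, up to 4 members of each biotype or list past the threshold and up to 2 of each list with a peak that was not past it. Genes and peaks outside it are said to have been picked after their values were seen, or, for MTCE.30, rpl-7A, T03F7.8, Y17G9B.5 and pqn-71, are named for sharing a window. Added after the data were examined were also the sorting of peaks into single kinds, the summit positions, the comparison of snoRNA with tRNA peaks, the gene lists without small RNA peaks, the 6-mers, motifs by kind of peak and the description of the mitochondrial genome. Alternatives were a stricter list (the 276 IDR peaks of highest signal), the 552 strongest peaks of each replicate alone, a window of 1000 bp upstream, overlap of the whole peak interval, other backgrounds, other motif windows, reciprocal overlap of 50% and ce10. Leaving out mitochondrial peaks and leaving out peaks at tRNA genes were added after the data were examined.

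The functions were tested on simulated data. Sets of 552 peaks with a known tRNA share gave that share back and passed the test in 20 of 20 runs at each of 3 shares. The placed summits always lay inside the window and were drawn singly. This checked the code that counts and tests peaks, not how clustered peaks affect the p values. In 100 unchanged sets drawn from relaxed peaks, 2.91% of biotype tests had an unadjusted p under 0.05, and after adjustment 0 sets had a biotype and 2 sets a gene list past it. A motif placed in 5% of windows passed in 20 of 20 runs. At random relaxed peaks with nothing placed, 26 of 300 motif tests (8.67%) had an unadjusted p under 0.05, so the flanking windows are not an exact null. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.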

Results

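Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map the binding sites of LIR-3, a zinc-finger protein related to LIN-26, in Caenorhabditis elegans. The animals were whole hermaphrodite L4 larvae, collected 48 hours after release from L1 starvation. Their strain carries a transgene that expresses LIR-3 fused at its C-terminus to GFP, and chromatin was precipitated with an antibody to GFP. All samples form 1 group of 2 biological replicates, so the comparisons below are between kinds of genomic region and between the replicates. On build ce11 the relaxed peak lists, which by design also hold background regions, contained 17311 peaks for replicate 1, 20601 for replicate 2 and 20360 for both replicates pooled. The irreproducible discovery rate (IDR) procedure of the submitters kept 552 peaks on ce11 and 774 on ce10. Sequencing depth was unknown, because the lists hold no read counts. Signal values are the authors' own scores per peak on a scale that is not stated. They rank, describe and compare peaks within a list, and between the replicate lists only their correlation was taken. Shares carry 95% Wilson intervals, which cover counting error over peaks only.

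The replicates placed most of their strongest peaks at the same positions. Of the 552 strongest peaks of replicate 1, 376 (68.1%, 95% interval 64.1 to 71.9) overlapped one of the 552 strongest of replicate 2, against a mean of 4.16% after circular shifts along each chromosome (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Within the 552 strongest peaks of each replicate lay 460 IDR peaks for replicate 1 and 447 for replicate 2. At the 551 IDR peaks present in both whole lists, the log2 signal values of the replicates had a Spearman rho of 0.514 and a Pearson r of 0.827 (two-sided permutation p = 1.0e-05 for each, the smallest that 100000 resamples can give). Without the 2 peaks farthest from the median of replicate 1, r was 0.822. These coefficients are across peaks, which are not independent replicates, and r fell to 0.582 when the 22 mitochondrial peaks were left out. The IDR peaks were also selected from these same 2 replicates, as the 552 highest-scoring peaks of their pooled list. Counts and coefficients at IDR peaks are therefore not an independent measure of replicate agreement.

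**Figure D1:**
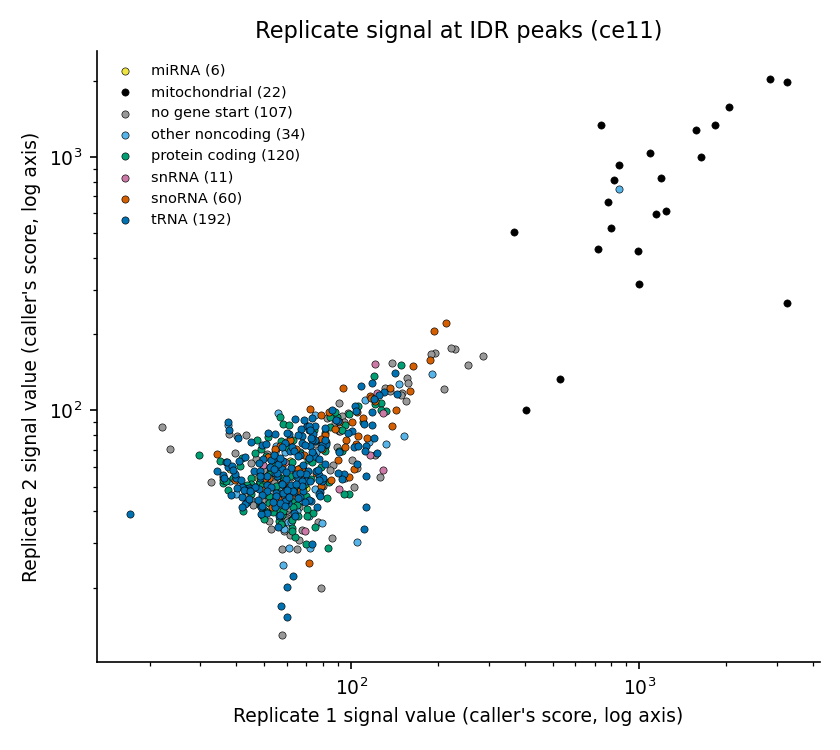
Signal values of the deposited replicate lists at IDR peaks on ce11, replicate 1 on the horizontal and replicate 2 on the vertical log axis, each point a peak coloured by the kind of gene start at its summit, with the number of peaks in the key. The 22 mitochondrial peaks fill most of the upper right corner, and Pearson's r of the log2 values was 0.827 with them and 0.582 without them.

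Most LIR-3-GFP peaks lay at gene starts, and most of these were starts of small RNA genes. Of the 552 IDR summits, 440 (79.7%, 76.2 to 82.9) fell from 500 bp upstream to 200 bp downstream of an annotated gene start, piRNA genes excluded, compared with 5038 of the 19684 relaxed peaks that no IDR peak overlaps (25.6%; odds ratio 11.4, 95% interval 9.24 to 14.2; two-sided Fisher's exact p = 5.86e-151). Sorted by 1 kind each, 192 nuclear peaks had a tRNA gene start in the window, 60 a snoRNA gene start, 11 an snRNA gene start and 6 a miRNA gene start. A further 120 had a protein-coding start without any of these, 34 had only another noncoding gene, 107 had no gene start, and 22 lay on the mitochondrial genome.

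**Figure D2:**
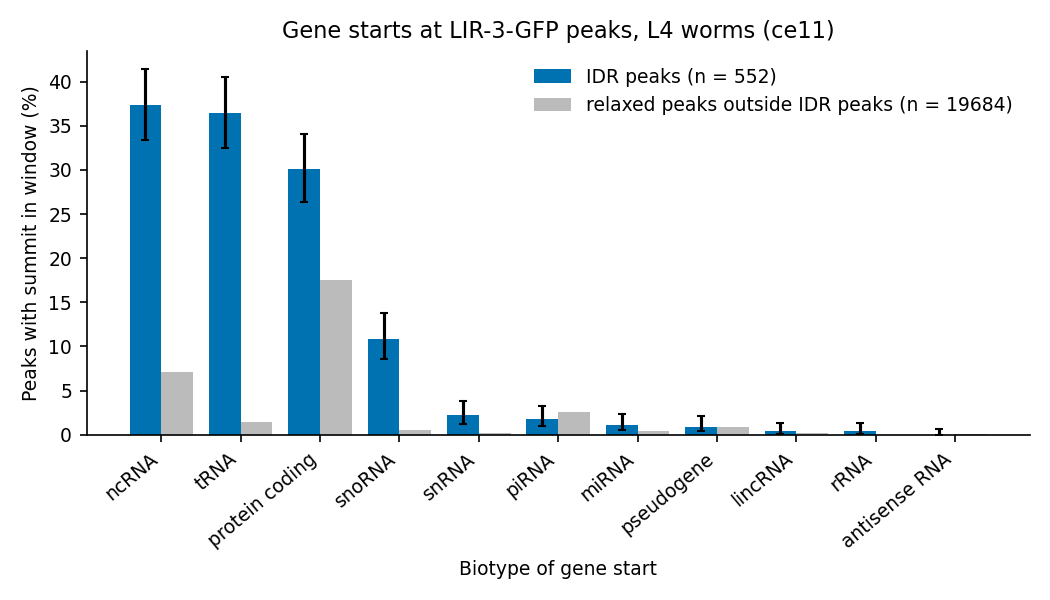
Percentage of peaks with the start of a gene of each biotype in the window, for the 552 IDR peaks (blue, bars of the 95% Wilson interval) and the 19684 relaxed peaks outside them (grey); a peak can count under several biotypes. tRNA starts were at 36.4% of IDR and 1.45% of relaxed peaks.

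Transfer RNA genes, whose nuclear copies are transcribed by RNA polymerase III, were the most enriched large class. A tRNA gene start lay at 201 of the 552 IDR peaks (36.4%, 32.5 to 40.5) and at 285 of the 19684 relaxed peaks (1.45%; odds ratio 39.0, 31.4 to 48.3; two-sided Fisher's exact p = 2.29e-193, Benjamini-Hochberg adjusted p = 2.52e-192 over 11 biotypes). In the 552 strongest peaks of each replicate's own list 175 (31.7%) lay at a tRNA gene start for replicate 1 and 193 for replicate 2. Of the 201, 9 were mitochondrial. Counted by gene, 237 of 634 annotated tRNA genes had an IDR summit in the window, whereas circular shifts gave a mean of 19.7 and at most 29 (permutation p = 0.000999). Among the 612 nuclear tRNA genes the number was 222 (36.3%, 32.6 to 40.2), and 509 (83.2%) had a summit of the pooled relaxed list. The tRNA genes with the highest peak signal were mitochondrial, MTCE.24 first and then MTCE.27, MTCE.28, MTCE.29 and MTCE.30, which share 1 peak. The strongest nuclear tRNA peaks, picked out after their values were seen, lay at F15G9.t1 and F15G9.t2 (X:9743520-9743731, signal 272.7, with 142.4 in replicate 1 and 141.1 in replicate 2) and at T23F1.t1 and T23F1.t2 (V:15464998-15465413, signal 255.3, with 144.8 and 116.3, a window shared with pqn-71). Most of the summits lay inside the transcribed part: at the 192 nuclear peaks the median position was 24.5 bp downstream of the nearest tRNA gene start, and 115 (59.9%) were within the gene. Many tRNA genes are near-identical copies of one another, so the peaks at single copies are uncertain where reads match several of them.

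Small nucleolar RNA genes, which guide chemical modification of ribosomal and other RNAs, were enriched as well. A comparison added after the data were examined found a higher mean signal at their IDR peaks than at those of nuclear tRNA genes. Starts of snoRNA genes were at 60 IDR peaks (10.9%, 8.54 to 13.7) and at 106 relaxed peaks (0.539%; odds ratio 22.5, 15.9 to 31.6; Fisher's exact test, adjusted p = 1.45e-50), covering 60 of 346 annotated snoRNA genes. The strongest were at ZK994.7 (V:8500408-8500726, signal 436.5, with 213.9 in replicate 1 and 221.7 in replicate 2), at C51F7.4 together with C51F7.3 (V:12303481-12303792, signal 396.6, with 193.6 and 205.4) and at C27H5.9 (II:7183998-7184215, signal 344.1, with 187.8 and 157.7). Mean log2 signal was 7.29 ± 0.53 (SD, 60 peaks) at snoRNA and 6.97 ± 0.36 (SD, 192 peaks) at nuclear tRNA genes, a difference of 0.33 (two-sided permutation p = 2.0e-05 over peaks). Both groups hold only peaks that passed IDR, whose lowest signal was 88.9, so the difference does not extend to all genes of either kind. Whether reads shared between tRNA copies changed the signal at tRNA genes was not tested. Unlike the summits at tRNA genes, 45 of the 60 (75%) lay upstream of the gene start, with a median position of -29.5 bp. Introns of protein-coding genes held 29 of the 60 snoRNA summits and also 85 of the 192 nuclear tRNA summits.

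**Figure D3:**
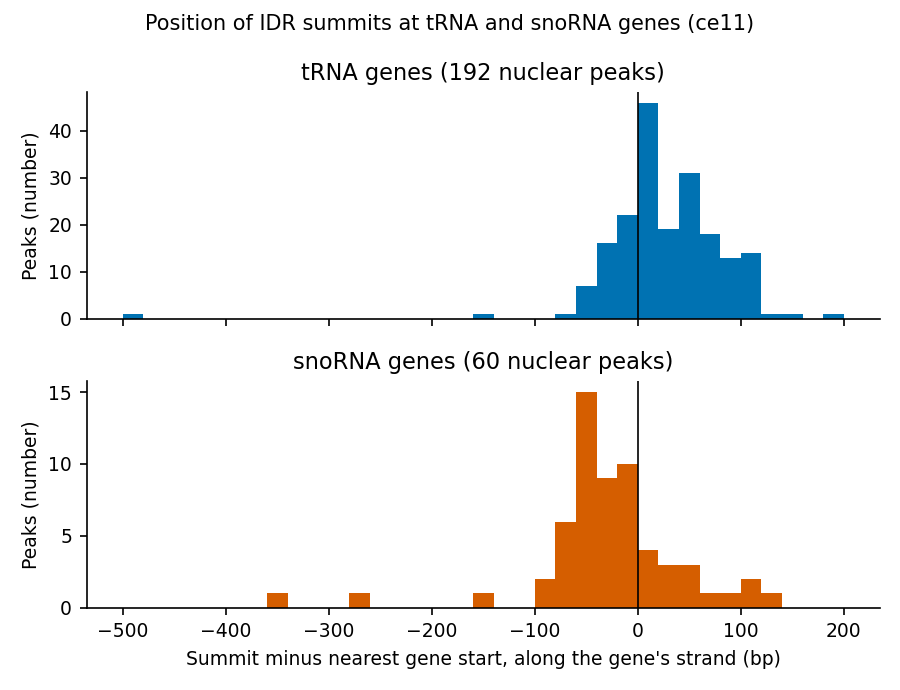
Number of IDR peaks by the distance in bp from the nearest gene start to the summit, along the gene's strand, for 192 nuclear tRNA peaks (top) and 60 snoRNA peaks (bottom), with the gene start at 0. The median is 24.5 bp at tRNA genes and -29.5 bp at snoRNA genes.

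Among the other noncoding classes, the broad class ncRNA passed the test with many peaks, and snRNA, miRNA and rRNA genes with few. Small nuclear RNA genes were at 12 IDR peaks (2.17% against 0.213% of relaxed peaks; odds ratio 10.4, 4.95 to 20.2; Fisher's exact test, adjusted p = 4.00e-08). They included R07E5.16 (III:10989527-10989763, signal 258.9), F54D8.7 (III:5080710-5081125, signal 185.0) and the SL2 spliced-leader genes sls-2.4 (I:4172193-4172500, signal 249.9) and sls-2.1 (II:5844668-5844879, signal 225.7). The broad class ncRNA was at 206 peaks (37.3% against 7.12%; adjusted p = 3.89e-86 by Fisher's exact test), many of them also at tRNA genes: without tRNA peaks, a setting added after the data were seen, it was 22.8% against 6.42%. Its strongest members were C08B11.13 (II:8028130-8028739, signal 1595, the strongest nuclear peak), C18A11.13 (X:8036263-8036535, signal 314.9), T03F7.14 (signal 277.3, in the same window as the snoRNA gene T03F7.8) and F15G9.8 (signal 272.7, overlapping F15G9.t1). Genes of miRNAs, among them cel-mir-4936, cel-mir-241, cel-mir-54 and cel-mir-55, were at 6 IDR peaks (1.09% against 0.396%; adjusted p = 0.0428 by Fisher's exact test), and the call was lost with a window of 1000 bp upstream (adjusted p = 0.208), without replicate 2 (adjusted p = 0.0670) and in the stronger 276 peaks, where the share was below that of relaxed peaks (0.362%). The rRNA class rested on MTCE.7 and MTCE.33, both mitochondrial (0.362% against 0.00508%; adjusted p = 0.00401 by Fisher's exact test), and had 0 peaks without the mitochondrial genome. The call was also lost without tRNA peaks (1 of 351, adjusted p = 0.0646 by Fisher's exact test), and with whole peak intervals the class was at 15 of 552 (2.72%). For piRNA genes (1.81% against 2.62%), lincRNA genes (0.362% against 0.168%), pseudogenes (0.906% against 0.884%) and antisense RNA genes (0 of 552, upper limit 0.691%, against 0.102%) the adjusted p was 0.340 or higher in Fisher's exact test. With the strongest peaks of 1 replicate alone, piRNA genes were at fewer peaks than the relaxed ones (1.27% for replicate 2, adjusted p = 0.0443; 0.906% for replicate 1, adjusted p = 0.00396; Fisher's exact test).

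Protein-coding starts were enriched more weakly. Among the gene lists tested, that of ribosomal proteins and a heat shock list that also takes in dnj and cct genes passed. Protein-coding starts were at 166 IDR peaks (30.1%, 26.4 to 34.0) against 17.6% of relaxed peaks (odds ratio 2.02, 1.67 to 2.44, Fisher's exact test, adjusted p = 4.63e-12). Some of these peaks were mitochondrial or also held a small RNA start. Without mitochondrial peaks they were at 152 of 530 (odds ratio 1.89, 1.55 to 2.29). Without tRNA peaks they were at 40.2% against 17.7% (odds ratio 3.13, 2.50 to 3.90). Both settings were added after the data were examined. Of 25 gene lists fixed before the data were examined, 2 passed an adjusted threshold of 0.05 against protein-coding genes with any relaxed peak. With this background the totals count only list members with such a peak, 46 of 81 ribosomal protein genes and 25 of 59 genes of the heat shock list. Ribosomal protein genes had an IDR peak at 13 of 46 (28.3% against 5.21% of other genes; odds ratio 7.17, 3.40 to 14.2; Fisher's exact test, adjusted p = 1.44e-05). Among them were rpl-3 (III:3867454-3867710, summit 270 bp upstream, signal 299.5, with 148.8 in replicate 1 and 151.8 in replicate 2), rpl-20 (IV:4749997-4750206, signal 236.5, a window shared with Y17G9B.5), rpl-15 (IV:654687-655102, signal 196.1) and rpl-35 (III:7854645-7854784, signal 185.7). Of the 13 windows, 3 also held a tRNA, snoRNA or snRNA start, and leaving such peaks out gave 10 of 46 (odds ratio 6.49, 2.81 to 13.6; Fisher's exact test, adjusted p = 0.000439). The heat shock list had a peak at 7 of 25 (28.0% against 5.34%; odds ratio 6.90, 2.40 to 17.5; Fisher's exact test, adjusted p = 0.00349). This list was chosen by gene symbol and includes dnj and cct genes as well as hsp genes. Of its hsp genes, only hsp-3 and hsp-110 had a peak, and its other members with a peak were cct or dnj genes. Among its members with peaks, hsp-3 (X:6091994-6092409, signal 139.1), hsp-110 (III:8446948-8447363, signal 135.8), the chaperonin subunit cct-1 (II:8185011-8185426, signal 113.2) and the DnaJ-domain gene dnj-9 (II:4851617-4852032, signal 97.1) had the highest signals. In the stronger 276 peaks the heat shock call was lost (2 of 25, adjusted p = 0.821 by Fisher's exact test), and with all protein-coding genes as background 6 lists passed. These were ribosomal proteins, heat shock, chromatin regulators, translation factors, mitochondrial respiration and chemoreceptors, of which the last had fewer peaks than other genes (3 of 1309, odds ratio 0.208, 0.0425 to 0.618; Fisher's exact test, adjusted p = 0.00604).

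The remaining lists did not pass with the main settings. Chromatin regulators had 6 of 36 (odds ratio 3.52, 1.18 to 8.71; adjusted p = 0.104 by Fisher's exact test), with set-16 (signal 180.6) and set-21 (signal 156.8, sharing its peak with rpl-7A and a small RNA gene). The list passed without replicate 2 (adjusted p = 0.00528), with a window of 1000 bp upstream (adjusted p = 0.0220), with overlap of the whole peak interval (adjusted p = 0.0298) and with all protein-coding genes as background (adjusted p = 0.00186; Fisher's exact test). Translation factors had 3 of 17, with iff-2 and eif-3.C, and mitochondrial respiration 3 of 23, with cox-5A and atp-1; both passed only with all protein-coding genes as background (adjusted p = 0.0340 for each, Fisher's exact test). Nuclear pore genes had 2 of 9 (npp-3 and npp-6), replication and cell cycle genes 2 of 26 (cdc-48.1 and pcn-1) and chemoreceptors 3 of 56 (sri-5 and srh-16 highest). A single member had a peak among tRNA synthetases (ears-2, 1 of 15), histones (his-37, 1 of 20), proteasome genes (rpn-3, 1 of 14, at the same peak as hsp-110), spliceosome genes (snr-1, 1 of 16), nuclear hormone receptors (nhr-47, 1 of 35) and heterochronic genes (lin-66, 1 of 2). The genes of the RNA polymerase III machinery had 0 of 6, V-ATPase genes 0 of 5, homeobox genes 0 of 9 and vitellogenins 0 of 1. No major sperm protein gene had a summit of the pooled relaxed list in the main window. Lists of tissue markers had no IDR peak either: 0 of 27 for collagens and cuticle, 0 of 10 for germ cells, 0 of 13 for body muscle, 0 of 26 for neurons, 0 of 9 for intestine and 0 of 3 for epidermis. These totals are the members with a relaxed peak, and the whole lists held 180, 56, 42, 138, 44 and 14 genes in the same order. The upper 95% limit of the odds ratio was 2.52 for collagens and 2.63 for neurons and higher for the shorter lists, so a depletion was not detectable.

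The X chromosome carried more peaks than its share of relaxed peaks. X held 173 IDR peaks (31.3%, 27.6 to 35.3) against 15.5% of relaxed peaks (odds ratio 2.49, 2.06 to 3.0; two-sided Fisher's exact p = 5.64e-20), and 29.7% on ce10. Of the 173, 109 lay at tRNA genes, and X holds 276 of the 634 annotated tRNA genes. When peaks at tRNA genes were left out of both sets, an alternative chosen after the data were seen, the X share was 18.2% against 15.2% (odds ratio 1.24, 0.930 to 1.64; Fisher's exact p = 0.134). On the autosomes, 161 of 357 summits (45.1%, 40 to 50.3) were in the chromosome arms, taken as the outer 25% at either end, against 48.1% of relaxed peaks (odds ratio 0.885, 0.713 to 1.1; Fisher's exact p = 0.261). With wider arms the share was lower than that of relaxed peaks (59.9% against 65.8%; Fisher's exact p = 0.0241), and against protein-coding gene starts the direction turned (45.1% against 44.3%; Fisher's exact p = 0.788).

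**Figure D4:**
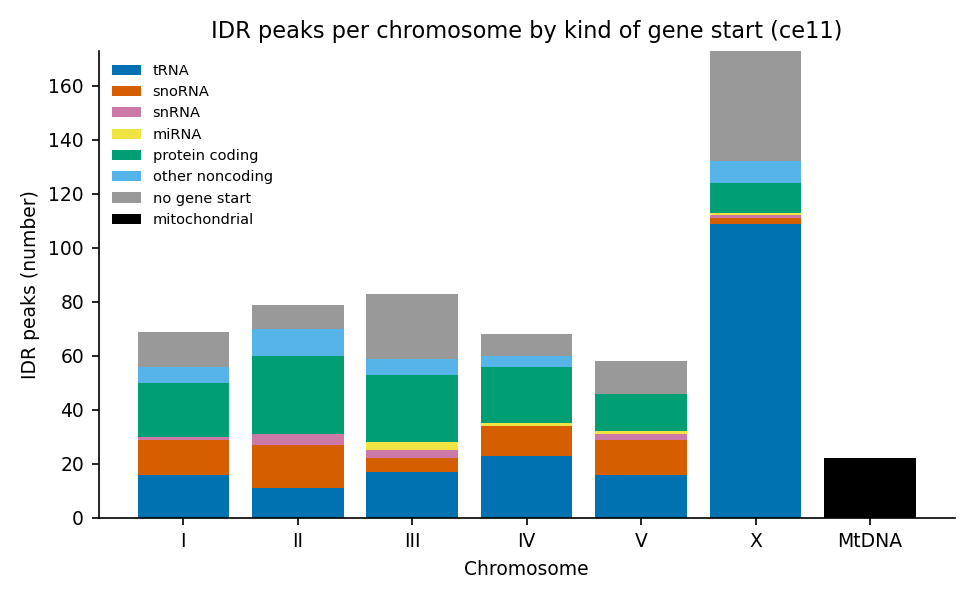
Number of IDR peaks on each chromosome (ce11), stacked by the kind of gene start in the window. X holds 173 peaks, 109 of them at tRNA genes and 41 without a gene start; the next highest is chromosome III with 83.

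Of the fixed motifs, the internal promoter boxes of tRNA genes had the highest shares at summits and were rarer beside them. Within 50 bp of the summit, the A box (TRGYNNARNNG) matched in 34.3% of 551 peaks and in 6.35% of windows 300 bp to the left (McNemar's exact test, adjusted p = 1.87e-29 over 15 motifs). The B box (GWTCRANNC) matched in 26.7% against 4.36% (adjusted p = 1.37e-23, same exact test). Boxes were also at snoRNA peaks, where the B box matched in 23 of 60 summits and 0 of 60 flanks. Of the motifs unrelated to tRNA promoters, TGCGTCTC matched in 4.36% against 0.181% (adjusted p = 7.75e-06, McNemar's exact test), and in 14 of the 120 peaks at protein-coding starts against 0 flanks. The E2F site (TTSSCGC) matched in 8.35% against 2.00% (adjusted p = 1.24e-05, same exact test). The Sp1-like CCCGCC was in 4.90% against 1.45% (adjusted p = 0.00263) and GAGAGAGA in 2.36% against 0.544% (adjusted p = 0.0277), both by McNemar's exact test and both lost with the control windows to the right and in the stronger 276 peaks. The GAGAGAGA call was also lost without tRNA peaks (adjusted p = 0.0964, McNemar's exact test). GATA sites (WGATAR) were less frequent at summits than beside them (11.6% against 18.5%; McNemar's exact test, adjusted p = 0.00450), a call that ended without tRNA peaks and with windows of 100 bp. The CAGCTG and CACGTG E boxes, TACTGTAG, the T block, TATA, CREB, AP-1 and the GTTTC core did not pass (adjusted p of 0.395 or higher, exact test). Of 2080 6-mers, scanned after the data were examined, 313 were more and 196 less frequent at summits, led by CGAACC (18.1% against 1.81%) and GTTCGA (21.1% against 3.63%), which match or overlap the B box. Summit windows were richer in GC than the windows beside them in most kinds of peak, with means of 47% against 35.1% at tRNA peaks, 53.4% against 36.5% at snoRNA peaks, 49.7% against 37.1% at protein-coding starts and 48.0% against 38.0% away from gene starts. They were not at snRNA peaks (42.4% against 43.1%) or mitochondrial peaks (27.86% against 27.91%). The motif tests were not adjusted for GC content.

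**Figure D5:**
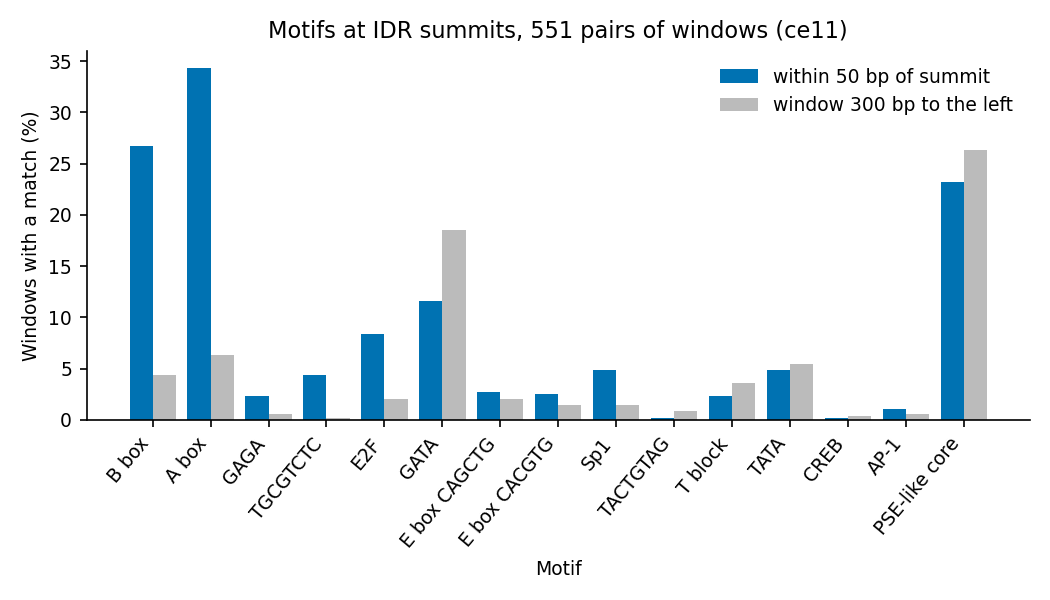
Percentage of windows with a match to each fixed motif, within 50 bp of the IDR summit (blue) and in the window 300 bp to the left (grey), over 551 pairs of windows. The A box reaches 34.3% at summits and 6.35% beside them.

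The strongest peaks of all were mitochondrial. The mitochondrial genome held 22 IDR peaks in 6 intervals that covered 87.9% of its 13794 bp, with signals from 357.1 to 5093. Of these peaks, 21 were among the 22 strongest of the list. With so much of this genome covered, the genes below mark positions within broad intervals and not separate sites. The pooled relaxed list held 23 mitochondrial peaks, and 0 of them lay clear of the IDR peaks, whose intervals cover most of this genome. No read counts were used, and what raised the signal there was not tested. The named protein-coding genes at these summits, with symbols from RefSeq, were CYTB (signal 5093), ND4 (3491), ATP6 (3160), COX1 (1617), ND3 (1612), ND2 (1402) and ND6 (607.3). The rRNA genes MTCE.7 (2629) and MTCE.33 (1837) and the tRNA genes MTCE.24, MTCE.27, MTCE.28, MTCE.29, MTCE.32, MTCE.15, MTCE.8, MTCE.9 and MTCE.2 were the others named by the rule. The strongest nuclear peak at a protein-coding start other than rpl-3 was at tasp-1 (III:10759125-10759343, signal 259.8), picked out after its value was seen.

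The tagged gene itself had no peak. In none of the 4 lists on ce11 did a peak lie within 500 bp of lir-3 (WBGene00003046, II:11183075-11184807). Its relatives lir-1 (II:7672005-7682363), lir-2 (II:7667267-7671909) and lin-26 (II:7682198-7684764), and unc-119 (III:10902641-10908935), the gene mutated in this strain, had no IDR peak. In the pooled relaxed list, lir-2 had no peak within 500 bp, and among its 20360 peaks the strongest peak was at rank 3300 for lir-1, 4158 for lin-26 and 3821 for unc-119.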

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

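For the tested shares and correlations that answer a comparison, 33 of 36 alternative values kept their direction and their side of the threshold. The arm share without mitochondrial peaks, among the 36, could not change because it uses autosomes only. Of the alternative counts, 23 of 25 lay within 1.5 times the main count, among them 774 for 552 IDR peaks on ce10 and 4 for 6 motifs in the stronger 276 peaks. Counts of motifs and of biotypes take only those more frequent at IDR peaks, which leaves out GATA sites and piRNA genes. Counts of gene lists take both directions. The tested values include the tRNA share (31.7% to 39.3%), the promoter share (68.1% to 85.3%), replicate overlap (58.7% to 68.8%) and the replicate rho (0.451 to 0.573). The settings without tRNA peaks and without mitochondrial peaks were chosen after seeing the data. Without tRNA peaks the X share was 18.2% and no longer passed; X held 109 of the 201 peaks removed. The arm share, not past the threshold in the main comparison, passed with wider arms (59.9% against 65.8% of relaxed peaks), and lay above rather than below its comparison when set against protein-coding gene starts (45.1% against 44.3%); the cause was not tested. The number of gene lists past the threshold was 1 in the stronger 276 peaks, which has fewer peaks, and 6 with all protein-coding genes as background, which counts genes without any relaxed peak; 1 of the 6, chemoreceptors, passed with fewer peaks than other genes. Among biotypes, the direction turned for miRNA genes in the stronger 276 peaks (0.362%), antisense RNA genes without replicate 2 (0.181%), pseudogenes with whole intervals (1.27%) and rRNA genes without mitochondrial peaks (0), whose 2 peaks are mitochondrial; the cause of the others, which rest on few peaks, was not tested. For single biotypes, 61 of 70 alternative values kept direction and threshold, 3 fell short of it, 2 newly passed it and 4 turned. Of 67 named genes with a peak, 64 had it among the 552 strongest of replicate 1 and 61 among those of replicate 2. Most of these genes were named for a high signal in a list made from both replicates, so these numbers are not an independent check. Depth is unknown, so which weak sites were missed cannot be judged. No paired analysis was possible because there is only 1 group.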

Other observations

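Among the tests below, those of tRNA copies, of the X-linked motif and of unannotated tRNA genes were set out before their results were seen, although 6-mers related to the X-linked motif had already been seen at IDR summits. The other tests and comparisons were chosen after the data were seen.

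Of the 607 nuclear tRNA genes with an isotype, cysteine tRNA genes had an IDR summit most often, at 11 of 13 (84.6%), followed by alanine at 21 of 34 (61.8%). Both differed from the other isotypes together (Fisher's exact test, adjusted p = 0.00998 and 0.0298 over 21 isotypes), and histidine, at 2 of 20 (10.0%), did not pass (adjusted p = 0.111). The tRNA genes on X had a summit at 126 of 276 (45.7%) and those on autosomes at 96 of 336 (28.6%; odds ratio 2.1, 95% interval 1.48 to 2.98; Fisher's exact p = 1.56e-05), while 84.1% and 82.4% had a relaxed summit. In these isotype and chromosome tests the gene was the unit, although the 222 nuclear tRNA genes with a summit lay at 192 peaks. Neighbouring or identical copies are not independent, so the p values are likely too small. Isotype, chromosome and copy number were not separated. Away from tRNA genes, 153 of 2080 6-mers were more and 108 less frequent at the 351 remaining summits than beside them. The lowest p values were those of the rarer AAAAAC (9.40% against 30.8%), AAAAAA (13.1% against 35.04%) and TTAAAA (7.69% against 25.9%), followed by the more frequent GACGCA (14.5% against 1.71%), ACGCAG (16.0% against 2.28%) and CTGCGC (12.8% against 0.855%). Of 304 snoRNA genes whose 36-mers are all unique, 53 had an IDR summit (17.4%, 13.6 to 22.1).

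The peaks at tRNA genes may mark binding, reads that match several copies, or regions enriched in any such experiment. Of 100 single-copy tRNA genes with no other tRNA gene within 1 kb, 23 had an IDR summit (23%, against at most 3% after circular shifts), above the bound set beforehand, but that bound was too weak because such genes still share shorter stretches with other copies, and 106 of 276 equally isolated multi-copy genes (38.4%) had one, a larger share (Fisher's exact p = 0.00664). Where tRNA genes have both boxes and no 50-mer found elsewhere in the genome, 8 of 46 had a summit (17.4%, 9.09 to 30.7; at most 6.52% after shifts), but with no 36-mer found elsewhere it was 0 of 14 (upper limit 21.5%; 2 of these 14 had a relaxed summit) against 128 of 342 with a shared 36-mer (37.4%), so shared reads may add to the peaks and cannot be told apart from binding without the read length. General binding to RNA polymerase III genes stays open: 4 of 24 other such genes had an IDR summit (16.7% against 1.04% of protein-coding genes; Fisher's exact p = 0.000108), namely rpr-1 (I:13463814-13464132, signal 268.8) and mrpr-1 (II:7200113-7200528, signal 152.2), the RNase P and RNase MRP RNA genes, and the signal recognition particle RNA genes srpr-1.2 and srpr-2.2, but 0 of the 16 5S rRNA genes had one (upper limit 19.4%), most of them repeats without unique 36-mers, and of the genes with only unique 36-mers rpr-1 and mrpr-1 had one and yrn-1, srpr-3 and rrn-4.16 did not, while U6 genes were not analysed here. Enrichment of open or highly transcribed regions in any GFP immunoprecipitation stays open, since 0 peak lists from a control immunoprecipitation were used here.

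Peaks away from gene starts were among the strongest on X, although over all IDR peaks they were not detectably more common there. They made up 41 of 173 peaks on X (23.7%) and 66 of 357 on autosomes (18.5%; odds ratio 1.37, 0.856 to 2.17; Fisher's exact p = 0.168). Of the 30 strongest nuclear peaks 15 had no gene start in the window, and 14 of these were on X, such as X:14525682-14526100 (signal 443.1, between genes, 730 bp from nspc-17, with the motif core GCGCAGGG), X:9465712-9465987 (signal 403.7, between genes, without it), X:6296405-6296777 (signal 394.7, in an intron of mom-1, with it) and X:11093986-11094338 (signal 394.4, between genes, with it). Unannotated tRNA genes are argued against at these X peaks, since 0 of the 41 had both an A box and a B box within 100 bp (upper limit 8.57%), compared with 172 of 192 peaks at tRNA genes (89.6%, 84.5 to 93.2). At autosomal peaks away from gene starts 9 of 66 had both boxes (13.6%, 7.34 to 23.9), so the argument does not extend to all of those. The core GCGCAGGG belongs to the motif at recruitment sites of the X-chromosome dosage compensation complex. It lay within 100 bp at 12 of the 41 X peaks (29.3%, 17.6 to 44.5) and at 0 of 66 autosomal peaks away from gene starts (Fisher's exact p = 3.19e-06). It also lay at 11 of 3050 relaxed X peaks (0.361%). Of the 14 strongest X peaks away from gene starts, 8 had the core and 6 did not. The X peaks away from gene starts may therefore include dosage compensation recruitment sites, as a hypothesis. Whether LIR-3 or any GFP immunoprecipitation enriches them was not tested.

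The peak lists had a gap around lir-3: on ce11, no peak lay from II:11151765 to 11212231 in replicate 1 (60.5 kb) or from II:11151061 to 11201820 in replicate 2 (50.8 kb), whereas the median gap between nuclear peaks was 3.10 kb and 2.66 kb. Gaps at least as long held 1.81% of the nuclear sequence in replicate 1, 1.51% in replicate 2 and 3.78% in the pooled list (51.5 kb there), so ordinary spacing is not excluded for a single locus. A candidate explanation is that extra copies of the tagged locus in the transgenic strain raised the control reads there, but control reads were not used here, so this cannot be told apart from other causes; the shorter gap of 50.8 kb is all that these lists give. No biological explanation was tested for the gap.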
